A study of Mus musculus with 90 samples.

How the data were processed

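Per the labels' protocols, 1000 double-sorted MmSCs, or 2 ng of RNA from whole tissue, went into a library, and the molecule was polyA RNA. Per the labels' protocols, libraries were built and sequenced by the methods of the Immunological Genome Project. Per the submitters' processing notes, reads were aligned with STAR 2.7.3a to mm10 and counted with featureCounts, whose version is not given in the sources used here. Strandedness, the handling of reads that match several places and the gene annotation behind the counts are not given in the sources used here. The authors' deposited counts were whole numbers per gene symbol, 55011 symbols in 90 libraries, and were used as they stood. Coordinates came from the GENCODE M21 annotation of mm10, which held 52936 of the symbols (96.2%).

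Of the count columns, 78 were matched to a sample by name. The other 12, of the cohort with both genotypes and AEX, were matched to their group only, since titles and library names of those samples disagree. Their replicates are named a, b and c here, since the numbers in the column names could not be tied to samples. No column was left unused. The smallest chi-square per gene between replicates was 2.75, so no library repeated another of its group. Pairs from different groups were not compared this way.

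Each cohort was fitted by itself in R 4.3.3 with edgeR 4.0.16, with filterByExpr at a minimum count of 10, TMM scaling and the robust quasi-likelihood test. P-values were adjusted by the Benjamini-Hochberg method over the genes of a comparison. The 22 comparisons were set before any value was seen. All TA groups shared 1 fit, as did vehicle and Yoda1 at 4 h and 6 h, so comparisons that share libraries are not independent. The interaction of genotype with day was tested jointly over days 1, 3 and 7, and its log2 values are the difference at day 3 minus the difference at day 1.

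Before any value was seen, 37 gene lists were fixed, 24 of responses and 13 of cell types. They held 723 symbols, of which 722 were found. They were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation, and adjusted over the lists of a comparison. Counts adjusted over the list alone used the same p-values within a list. The sets carried between cohorts were the called genes that were higher in a source comparison, at most 200 with the largest fold.

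Genes were named by a rule written before any value was seen: Piezo1 in every group, and up to 8 called genes per direction with the largest fold. The latter needed a mean of at least 10 CPM in the higher group and no overlap between the libraries compared, except in the interactions, and left out predicted genes, clones, pseudogenes and mitochondrial transcripts. Up to 4 called members of a described list with the largest fold were added, or up to 2 with the smallest p where none was called. Sex-linked genes were named only under their list. Some genes that the rule names are not reported here.

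The alternatives were RLE scaling, DESeq2 1.42.0, no filter on low counts, each library left out, the replicate number as a block, the estimated correlation, and other sizes and sources of the carried sets. Added after results were seen were fits without the genes that varied together between libraries, with their score or Y-linked expression as a covariate, with counts thinned to the shallowest library, and with only the libraries of the groups compared.

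The tests were also run on simulated counts with about 200 genes changed by log2 1 or 2. For AEX, 43.8% of changes of log2 1 and 88.8% of log2 2 were recovered among 12533 genes, and for 4 h of Yoda1 64.6% and 90% among 13471 genes. False calls were 12 of 141 calls for AEX and 11 of 165 for 4 h of Yoda1. Each gene was drawn independently, so the simulated counts hold no variation shared between genes. The shares recovered may overstate what the real libraries could show, also where fewer genes change.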

Results

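The counts covered 90 mouse libraries in 29 groups of 2 to 4. In 44 of them, 1000 mesenchymal stromal cells sorted from hindlimb muscle (MmSCs, positive for PDGFRa and Sca1, negative for CD31 and CD45) were sequenced together. The others were whole tissue: tibialis anterior (TA) and quadriceps muscle (26 libraries), and heart and liver (20). Counts per library ran from 1806248 to 10258234 in MmSCs, from 4051973 to 10226407 in muscle and from 27461930 to 38376123 in heart and liver. The groups had 3 libraries each, except 2 for Yoda1 at 2 h and 4 each for TA muscle at day 1 and for liver. AEX stands for acute exercise, EXT for exercise training, SED for sedentary controls and CTX for cardiotoxin, a snake venom toxin that destroys muscle fibres. Levels are given as CPM, counts scaled to library size with TMM factors, as mean ± SD. A gene is called where edgeR's quasi-likelihood test gave an adjusted p under 0.05, and a gene list where limma's camera did. No label states separate animals for the replicates, so p-values measure the spread between samples.

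Piezo1, the mechanically gated cation channel this series is about (chromosome 8 from 122481698 to 122551329, mm10), was not called lower in any group labelled mutant (Pdgfra-Cre with floxed Piezo1) against WT (Pdgfra-Cre with intact Piezo1). In MmSCs it measured 62.4 ± 15.4 against 43.0 ± 4.49 CPM at rest (mutant against WT, n = 3 each), 71.7 ± 13.0 against 54.3 ± 5.06 CPM after AEX, and 53.7 ± 1.5 against 65.3 ± 5.37 CPM after CTX (log2 -0.28, adjusted p = 0.190). In TA muscle it measured 40.8 ± 6.82 against 46.4 ± 6.05 CPM at day 1, 29.1 ± 8.41 against 27.9 ± 5.84 CPM at day 3 and 20.7 ± 3.31 against 21.7 ± 0.825 CPM at day 7. It measured 12.6 ± 1.80 against 11.3 ± 4.98 CPM in quadriceps, 19.9 ± 3.83 against 21.3 ± 3.58 CPM in uninjured heart, 14.2 ± 3.23 against 17.1 ± 0.487 CPM in heart at day 3 and 2.99 ± 1.67 against 3.66 ± 2.46 CPM in liver. Counts per gene cannot show the loss of floxed exons, and whole tissue holds many cells without the Cre driver. Because these counts do not show the knockout, the groups are called labelled mutant throughout. In the other MmSCs, Piezo1 measured 32.0 ± 9.96 against 19.5 ± 2.95 CPM (AEX against SED), 94.5 ± 5.28 against 83.5 ± 4.23 CPM (EXT against SED), 105 ± 3.76 against 101 ± 7.39 CPM (Yoda1 4 h against vehicle) and 111 ± 13.4 against 101 ± 7.39 CPM (6 h against the same vehicle). At 2 h of Yoda1 it was lower (26.6 ± 6.0 against 115 ± 17.8 CPM, log2 -2.09, adjusted p = 0.00102).

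The first comparison asked how 1 bout of exercise changed MmSCs 1 day later (3 AEX against 3 SED libraries). Tnc, a matrix glycoprotein of remodelling tissue, rose most (780.1 ± 590.2 against 5.87 ± 1.56 CPM, adjusted p = 0.0269). Timp1, a secreted inhibitor of matrix metalloproteases, followed (563 ± 344 against 24.7 ± 4.50 CPM, log2 4.51, adjusted p = 0.0395). F2rl1, a receptor opened by proteases (chromosome 13 from 95511732 to 95525227), rose from 3.81 ± 0.882 to 42.4 ± 24.6 CPM (log2 3.46, adjusted p = 0.0233). Other large rises were in the WNT-induced factor Ccn4, the sphingosine kinase Sphk1, the transcription factor Runx1, Uck2 and the cytokine Clcf1 (log2 3.15, 3.14, 2.64, 2.08 and 1.95, adjusted p 0.0203 to 0.0397). The stress and adhesion genes Ier3 (log2 1.64, adjusted p = 0.0206) and Icam1 (log2 0.72, adjusted p = 0.0329) also rose. The clock repressor Bhlhe41 was higher (log2 1.06, adjusted p = 0.0211). Genes of resting stroma fell: the surface marker Thy1 (45.6 ± 13.6 against 132 ± 18.3 CPM, log2 -1.54), Dpp4, Cd55 and Ly6c1 (log2 -1.06, -0.91 and -0.75). Lower too were Fn1 (1236 ± 258 against 2828 ± 335 CPM, log2 -1.19) and the BMP-family factors Bmp3 and Gdf10 (log2 -2.03 and -1.0), with adjusted p 0.0203 to 0.0395. Aph1b, Il18, Pcdh20 and Car8 fell as well (log2 -2.09, -1.98, -1.84 and -1.75).

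Of 12777 genes tested after AEX, 94 were called, 33 higher and 61 lower. Stromal cell markers were lower as a list (median log2 -0.38, adjusted p = 2.99e-06, 0.377 with an estimated correlation). Among stromal cell markers, 0 were higher, 4 lower and 15 not called, or 1 and 10 adjusted over the list alone. ER stress and ATF4 targets (median log2 0.43, adjusted p = 6.06e-06), NF-kB targets (median log2 0.35, adjusted p = 1.63e-04), and heat shock genes (median log2 0.44, adjusted p = 9.70e-04) were higher. So were TGF-beta genes (median log2 0.44, adjusted p = 7.02e-04) and chemokines and cytokines (median log2 0.26, adjusted p = 0.0186). These had adjusted p between 0.377 and 0.539 when the correlation was estimated. The monocyte chemokine Ccl7 was not called (120.0 ± 72.7 against 21.0 ± 7.05 CPM, log2 2.52, adjusted p = 0.159), nor was Ccl2, chosen after values were seen (476 ± 341 against 53.8 ± 31.7 CPM, log2 3.15, adjusted p = 0.206). Replicate 3 of both groups carried Y-linked reads and the others did not, and 89 genes were called with Y-linked expression as a covariate. The count depended on single libraries: 1, 1 and 18 without SED 1, 2 and 3, and 975, 10 and 37 without AEX 1, 2 and 3. The balance turned without AEX 1, with 599 genes higher and 376 lower. Of the 61 lower genes 10 belonged to a set that varied together between single libraries, whose score was -0.484 to -0.239 after AEX and 0.115 to 0.653 in SED, and 75 genes were called without that set. DESeq2 called 432.

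Training was compared with SED in MmSCs of another cohort (n = 3 each). Genes of matrix turnover rose: Mmp3 (358 ± 15.8 against 174 ± 12.1 CPM, log2 1.04, adjusted p = 2.67e-04), the protease inhibitor Timp1 (244 ± 28.3 against 121 ± 7.95 CPM, log2 1.01), the collagen-digesting cathepsin Ctsk (618 ± 28.0 against 327 ± 73.0 CPM, log2 0.92) and Mmp14 (0.60), with adjusted p 2.67e-04 to 0.0369. Ereg, a ligand of the EGF receptor, went from 2.14 ± 0.0794 to 10.7 ± 4.05 CPM (log2 2.31, adjusted p = 0.0153). The neutrophil chemokine Cxcl2 went from 102 ± 4.38 to 171 ± 23.4 CPM (log2 0.75, adjusted p = 0.0134). Lhfpl2, Neu2, the imprinted RNA H19 (chromosome 7 from 142575529 to 142578143), Msc, Ccn4, Tnc and the glucose transporter Slc2a1 rose too (log2 1.27, 1.56, 1.42, 1.05, 1.02, 0.81 and 0.76). The intermediate filament gene Des (11.9 ± 0.638 against 30.1 ± 5.20 CPM, log2 -1.34), the chemokine scavenger Ackr2 (53 ± 1.99 against 112 ± 9.19 CPM, log2 -1.08), Cdc25b, Rrad, Krt80 and Cish fell (log2 -1.55, -1.27, -1.26 and -0.93). So did the small heat shock gene Hspb1 and the immediate early genes Zfp36 and Fosb (log2 -0.98, -0.75 and -0.58, adjusted p 0.0287 to 0.0490).

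With training, 62 of 12802 genes were called, 36 higher and 26 lower. Matrix proteases and inhibitors were higher as a list (median log2 0.02, adjusted p = 3.63e-05, 0.367 with an estimated correlation). Among matrix proteases and inhibitors, 4 were higher, 0 lower and 15 not called, or 5 and 1 adjusted over the list alone. Collagens and matrix were also higher (median log2 0.29, adjusted p = 1.00e-05, 0.448 with an estimated correlation), while immediate early genes were lower (median log2 -0.32, adjusted p = 1.55e-05, 0.448 with an estimated correlation). Among immediate early genes, 0 were higher, 2 lower and 25 not called, or 3 and 11 adjusted over the list alone. Without EXT 1, 2 and 3 the counts were 12, 22 and 23, and without SED 2 and SED 3 they were 18 and 117. DESeq2 called 218.

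**Figure D1:**
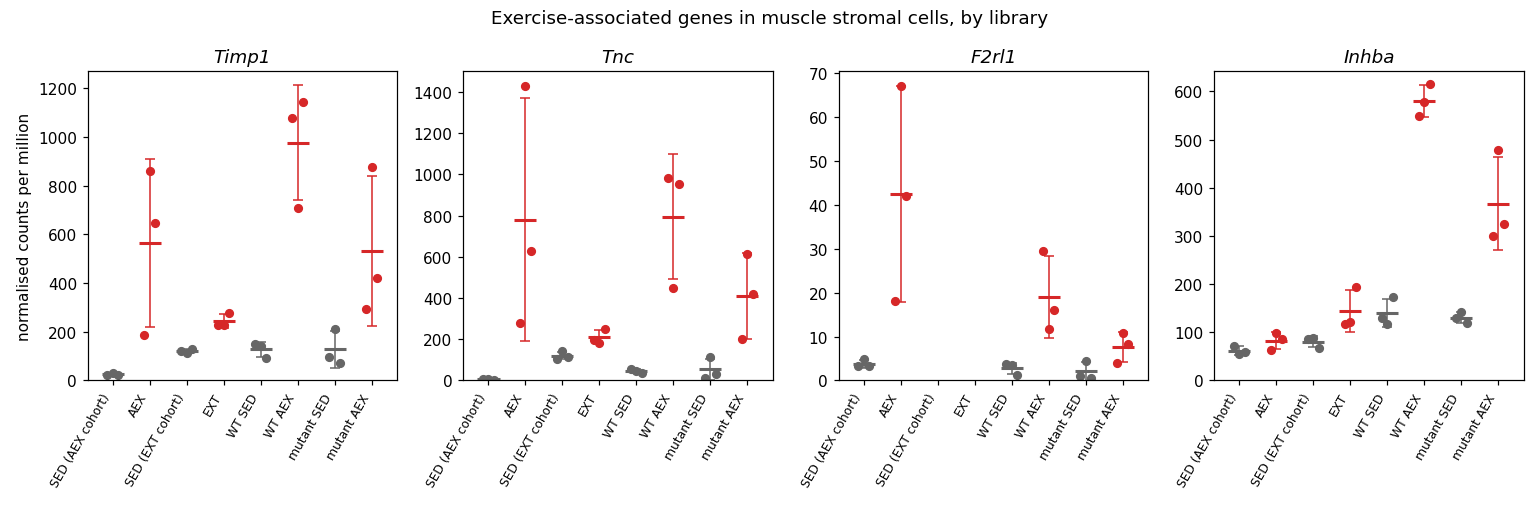
Normalised CPM of Timp1, Tnc, F2rl1 and Inhba in each MmSC library (points) of the exercise groups, with means and SD bars. Timp1 had a mean of 563 CPM after AEX against 24.7 in its SED group, and 976 against 129 CPM in the WT cohort, while F2rl1 was under the expression filter in the EXT cohort.

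In a cohort with both genotypes, AEX was compared with SED within Pdgfra-Cre WT mice (n = 3 each). Timp1 rose again (976 ± 235 against 129 ± 30.3 CPM, log2 2.92, adjusted p = 0.0274), as did F2rl1 (19.1 ± 9.33 against 2.81 ± 1.29 CPM, log2 2.75). Inhba, which encodes a subunit of activin (chromosome 13 from 16011851 to 16031621), also rose (580.3 ± 33.2 against 140.1 ± 29.1 CPM, log2 2.05, adjusted p = 3.04e-05). The smooth muscle actin Acta2 was higher as well (38.8 ± 6.83 against 6.17 ± 4.25 CPM, log2 2.64). The neutrophil chemokine Cxcl1 went from 1519.6 ± 196 to 3609 ± 724 CPM (log2 1.25, adjusted p = 0.0237). Il33, an alarmin of stromal cells, went from 449 ± 108 to 969 ± 85.0 CPM (log2 1.11, adjusted p = 0.0269), and Tslp rose too (log2 1.32, adjusted p = 0.0458). Genes of amino acid supply under ATF4 rose (Asns (1.56), Psat1 (1.17) and Mthfd2 (0.86)), with the chaperones Manf and Hspd1 (log2 1.02 and 0.91). The glycolysis genes Eno1 (1.17), Pgk1 (1.03), Ldha (0.77) and Aldoa (0.73) rose too, and all of these had adjusted p 0.00442 to 0.0446. Matrix genes moved both ways, with Thbs4, Lox and Col8a1 higher (log2 1.89, 1.77 and 1.40) and Col1a2, Mfap4 and Cpz lower (log2 -1.09, -1.44 and -1.91). Ighm, an antibody heavy chain, Aoc3, Sox11, Cd55 and the interferon-induced Cmpk2 were lower (log2 -3.0, -1.56, -1.55, -0.71 and -1.37).

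In these WT mice 147 of 14821 genes were called, 87 higher and 60 lower. ER stress and ATF4 targets formed the only list whose call held with an estimated correlation (median log2 0.67, adjusted p = 5.31e-15, 0.0239 with an estimated correlation). Among ER stress and ATF4 targets, 4 were higher, 0 lower and 21 not called, or 17 and 1 adjusted over the list alone. Chemokines and cytokines were higher (median log2 0.64, adjusted p = 2.25e-06, 0.154 with an estimated correlation). Among chemokines and cytokines, 3 were higher, 0 lower and 19 not called, or 9 and 2 adjusted over the list alone. Interferon-stimulated genes were lower (median log2 -0.52, adjusted p = 9.79e-12, 0.173 with an estimated correlation). Among interferon-stimulated genes, 0 were higher, 1 lower and 30 not called, or 0 and 9 adjusted over the list alone. Mitochondrial respiration (median log2 0.45, adjusted p = 2.77e-14, 0.147 with an estimated correlation) and glycolysis genes (median log2 0.49, adjusted p = 5.21e-08, 0.147 with an estimated correlation) were higher. Single libraries moved the count to 30, 44 and 230 (without SED a, b and c) and to 63, 36 and 15 (without AEX a, b and c). Without SED c 71 genes were higher and 159 lower. DESeq2 called 443.

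In the labelled mutants, AEX against SED called 24 genes, 22 higher and 2 lower (n = 3 each). Inhba rose here as well (367 ± 96.3 against 130.4 ± 11.9 CPM, log2 1.49, adjusted p = 0.00319), and the interferon-inducible GTPase Iigp1 (124 ± 21.9 against 298 ± 88.0 CPM, log2 -1.27) and Efhd1 (-0.83) fell. The other largest rises were in Nubp1 (1.84), Tmem259 (1.65), Larp6 (1.56), Prmt3 (1.51), Lsm4 (1.47), Nop9 (1.43) and Usp39 (1.40), with adjusted p 0.0184 to 0.0408. Interferon-stimulated genes were lower as a list (median log2 -0.61, adjusted p = 1.03e-13, 0.425 with an estimated correlation). A set of genes that varied together between single libraries in other cohorts made up 68.8% of the higher genes outside its seeds, and 2 genes were called without it. With the score of that set as a covariate 0 genes were called. The score was -1.20 to -0.501 in SED and 0.106 to 0.430 after AEX, so the covariate also removes part of the exercise difference. Without SED b or c the count was 2, and without AEX a, b and c it was 11, 1 and 1. DESeq2 called 75.

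At rest, labelled mutant and WT MmSCs differed in 1 gene, Chpf, which builds chondroitin sulfate chains (54.4 ± 6.73 against 122 ± 15.9 CPM, log2 -1.17, adjusted p = 0.0244). Collagens and matrix genes were lower in the labelled mutants as a list (median log2 -0.65, adjusted p = 1.14e-16, 0.207 with an estimated correlation). Among collagens and matrix, 0 were higher, 0 lower and 33 not called, or 0 and 17 adjusted over the list alone. Cell cycle genes were lower (median log2 -1.65, adjusted p = 5.19e-07, 0.569 with an estimated correlation), with a wide spread within the groups: Plk1 was at 6.17, 9.96 and 0 CPM in WT a, b and c and at 2.33, 4.44 and 0.0990 CPM in mutant a, b and c. Immediate early genes (median log2 0.28, adjusted p = 2.99e-04) and heat shock genes (median log2 0.30, adjusted p = 8.44e-04) were higher, with adjusted p 0.569 and 0.569 with an estimated correlation. With the score of a set of genes that varied together between libraries as a covariate, their means turned to -0.14 and -0.10, and the cell cycle list was not called (mean -0.46). Chpf belongs to that set, and without it no gene was called. The unadjusted p was under 0.05 for 1094 genes, and DESeq2 called 53. Without WT a, WT b, mutant b or mutant c no gene was called, without WT c 91 and without mutant a 18. With 3 against 3, random regroupings are too few to show chance below a share of 10%.

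After AEX, edgeR called 0 of 14821 genes between labelled mutant and WT MmSCs, with unadjusted p under 0.05 for 814, and DESeq2 called 2. Of simulated changes in this comparison, 36.4% at log2 1 and 71.7% at log2 2 were recovered among 14359 genes. As lists, ER stress and ATF4 targets (median log2 -0.42, adjusted p = 5.88e-10, 0.0805 with an estimated correlation), cholesterol synthesis genes (median log2 -0.58, adjusted p = 5.88e-10, 0.395 with an estimated correlation) and chemokines and cytokines (median log2 -0.26, adjusted p = 5.87e-04, 0.395 with an estimated correlation) were lower in the labelled mutants. The interaction of genotype with AEX, which tests whether the response to exercise differed, had 0 called genes by edgeR, 884 with unadjusted p under 0.05, and 1 by DESeq2. Without WT SED c the interaction had 4. A negative value means a less positive change with AEX in the labelled mutants than in WT. The lists were negative for chemokines and cytokines (median log2 -0.52, adjusted p = 6.15e-05, 0.340 with an estimated correlation) and heat shock genes (median log2 -0.56, adjusted p = 4.59e-07, 0.340 with an estimated correlation). Heat shock genes, and glycolysis and hypoxia genes, were higher in the labelled mutants at rest, so their values in this interaction also hold that difference. Among chemokines and cytokines, 0 were higher, 0 lower and 22 not called, or 0 and 3 adjusted over the list alone. ER stress and ATF4 targets (median log2 -0.52, adjusted p = 3.14e-07, 0.215 with an estimated correlation) and glycolysis and hypoxia genes (median log2 -0.47, adjusted p = 7.49e-06, 0.340 with an estimated correlation) were negative too. Red blood cell genes had a negative median (-0.11) but a positive mean (0.02). No list of this interaction held with an estimated correlation.

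Yoda1, a small molecule that opens Piezo1, was applied at 25 µM to sorted MmSCs in brief culture, to ask whether the channel alone starts an inflammatory reaction. The labels name WT mice at 2 h and give no genotype at 4 h and 6 h. How long the vehicle libraries were cultured is not given in the sources used here, so time in culture was not separated from Yoda1. At 2 h (2 libraries, against 3 vehicle libraries that the labels name 0 h), the monocyte chemokines Ccl2 and Ccl7 rose. Ccl2 measured 7977 ± 302 against 3531 ± 269 CPM, log2 1.18, adjusted p = 7.06e-04, and Ccl7 5176 ± 302 against 1705 ± 232 CPM, log2 1.60, adjusted p = 5.95e-04. The feedback and early genes Spry2 (585 ± 13.2 against 134 ± 19.6 CPM, log2 2.13, adjusted p = 2.92e-04), Dusp1 (1.01), Ier5 (1.30), Klf6 (0.87) and Myc (0.86) also rose (adjusted p 0.00301 to 0.0372). The ER stress gene Herpud1 (729 ± 41.5 against 286 ± 33.9 CPM, log2 1.35, adjusted p = 7.95e-04) and the interferon-induced Ifit1 (1.69) and Ifit3 (2.09) were higher. So were the matrix protein Spp1 (2.94), Mmp3 (1.24), the heat shock genes Hspa8 (0.80) and Dnajb1 (0.80) and Inhba (0.99). Collagens fell, among them Col5a2 (-1.62), Col4a2 (-1.61), Col4a1 (-1.53) and Col6a2 (-1.48), together with the receptors Pdgfrb (92.3 ± 0.320 against 334 ± 45.2 CPM, log2 -1.86, adjusted p = 5.95e-04) and Axl (295 ± 3.63 against 762 ± 57.5 CPM, log2 -1.37). The NF-kB genes Nfkb2 (-1.05), Ier3 (-1.0), Relb (-0.86) and Vcam1 (-0.74), the cytokine Csf1 (-1.0), Cx3cl1 (-2.19) and the glycolysis gene Gapdh (37.4 ± 4.70 against 139 ± 25.4 CPM, log2 -1.88) fell as well (adjusted p 0.00110 to 0.0348).

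At 2 h, 1437 of 12782 genes were called, 678 higher and 759 lower. Collagens and matrix were lower as a list (median log2 -0.85, adjusted p = 1.10e-17, 0.602 with an estimated correlation). Among collagens and matrix, 2 were higher, 20 lower and 11 not called, or 2 and 28 adjusted over the list alone. Mitochondrial respiration genes were higher (median log2 0.46, adjusted p = 7.27e-05, 0.602 with an estimated correlation). Among mitochondrial respiration genes, 5 were higher, 0 lower and 24 not called, or 10 and 0 adjusted over the list alone. The Yoda1 libraries held 1806248 and 3416913 counts against 4667436 to 5621061 in vehicle. After all libraries were thinned to the shallowest, 1482 genes were called. Without vehicle 1, 2 and 3 the count was 272, 690 and 334. Without Yoda1 1 or 2 it was 3047 and 2962, where the remaining sample was assumed to vary like the vehicle samples. In simulations 31.2% of changes of log2 1 and 67.4% of log2 2 were recovered among 12137 genes.

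In a separate cohort, 4 h of Yoda1 (n = 3 each) raised the inflammatory cytokines Il6 (237 ± 5.20 against 107 ± 10.8 CPM, log2 1.15, adjusted p = 1.31e-12), Lif (171 ± 16.4 against 96.0 ± 15 CPM, log2 0.83, adjusted p = 1.11e-06) and Cxcl1 (1304 ± 81.4 against 776 ± 85.2 CPM, log2 0.75, adjusted p = 4.21e-04). The prostaglandin synthase Ptgs2 also rose (559 ± 27.4 against 319 ± 38.7 CPM, log2 0.81). The early nuclear receptor Nr4a3 (log2 0.97, adjusted p = 5.89e-08), Ier3 (0.51), Ier5 (0.69), Nfil3 (0.98) and Adamts1 (0.73) and the heat shock genes Hspa1b (0.97), Hspa1a (0.46), Dnajb1 (0.34) and Hsp90aa1 (0.26) rose (adjusted p 1.02e-10 to 0.00270). Ccl2 (1789 ± 10.0 against 1728 ± 95.7 CPM, log2 0.05, adjusted p = 0.755) and Ccl7 (537 ± 47.7 against 571 ± 28.2 CPM, log2 -0.09, adjusted p = 0.702), added because they rose at 2 h, were not called. The largest folds were in Rnf187 (58.7 ± 15.8 against 15.9 ± 0.897 CPM, log2 1.87, adjusted p = 1.10e-09), Tmem259 (14.2 ± 4.83 against 3.84 ± 0.215 CPM, log2 1.87), Nsmce3 and Arrdc4 (log2 1.57 and 1.52). Klf10 (log2 -0.72, adjusted p = 9.99e-08), the stretch target Ccn2 (log2 -0.45, adjusted p = 1.81e-05), Pdgfrb (log2 -0.42, adjusted p = 2.28e-06) and Angptl4 (log2 -0.88, adjusted p = 4.04e-04) fell. So did Abcg1, Ch25h, the replication gene Mcm6 and Timp1 (log2 -1.07, -0.92, -0.60 and -0.44). In all 785 of 13756 genes were called, 493 higher and 292 lower.

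Heat shock genes were higher as a list at 4 h (median log2 0.15, adjusted p = 9.86e-07, 0.193 with an estimated correlation). Among heat shock genes, 7 were higher, 0 lower and 9 not called, or 8 and 0 adjusted over the list alone. Immediate early genes (median log2 0.22, adjusted p = 1.69e-05, 0.193 with an estimated correlation) and chemokines and cytokines (median log2 0.09, adjusted p = 0.00252, 0.193 with an estimated correlation) were also higher. Among immediate early genes, 8 were higher, 2 lower and 16 not called, or 12 and 2 adjusted over the list alone. Mural cell markers had a positive median (0.03) and a negative mean (-0.15) and were not called. Of the genes higher at 4 h, 21.4% belonged to the set that varied together between single libraries in other cohorts, against 1.23% of all genes. Without that set, which Rnf187 helped define, 622 genes were called. With the score of that set as a covariate 3 genes were called. The score differed between the vehicle (-1.11 to -0.618) and Yoda1 libraries (0.0834 to 0.550), so the covariate also removes the treatment. Without vehicle 1 the count was 507 and without Yoda1 3 it was 456.

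At 6 h against the same vehicle libraries, Il6 (202 ± 18.9 against 107 ± 10.8 CPM, log2 0.92, adjusted p = 4.74e-11), Tnc (616 ± 46.8 against 262 ± 6.64 CPM, log2 1.23, adjusted p = 2.78e-13), Inhba (205 ± 31.2 against 92.7 ± 12.9 CPM, log2 1.14), Il11 (1.31) and Cxcl5 (0.67) were higher. The metalloproteases Mmp12 (27.9 ± 8.02 against 5.24 ± 2.91 CPM, log2 2.41) and Mmp10 (11.6 ± 6.23 against 2.18 ± 1.12 CPM, log2 2.41), the amino acid transporter Slc7a11 (128 ± 9.57 against 57.6 ± 5.41 CPM, log2 1.14, adjusted p = 4.74e-11), and the mTOR inhibitor Ddit4 (log2 1.24, adjusted p = 5.54e-05) rose. Mthfd2, Sgk1 and the p53 targets Zmat3 and Plk2 rose as well (log2 0.65, 0.65, 0.72 and 0.65). Icam1 (188 ± 8.08 against 342 ± 11.7 CPM, log2 -0.87, adjusted p = 2.17e-12), the NF-kB inhibitor Nfkbia (log2 -0.57, adjusted p = 3.03e-08), and Ccl11 (log2 -0.53, adjusted p = 2.96e-06) fell. So did Ccl2 (1375 ± 172 against 1728 ± 95.7 CPM, log2 -0.33, adjusted p = 0.00132) and Ccl7 (438 ± 65.0 against 571 ± 28.2 CPM, log2 -0.38, adjusted p = 0.0184). The collagens Col1a2 (-0.52), Col3a1 (-0.49) and Col1a1 (-0.48), the stromal markers Cd34 (-0.56), Pi16 (-0.53) and Clec3b (-0.58), Cavin1 (471 ± 35.0 against 865 ± 3.34 CPM, log2 -0.88) and the interferon-stimulated Usp18 (-1.72), Iigp1 (-1.32) and Oasl2 (-0.86) were lower (adjusted p 2.17e-12 to 0.00801). Rnf187, which helped define the set that varied between libraries, was again among the largest rises (log2 2.01, adjusted p = 4.74e-11).

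At 6 h 1822 genes were called, 898 higher and 924 lower, and 28 were called with that score as a covariate. Stromal cell markers were lower (median log2 -0.33, adjusted p = 2.63e-10, 0.0475 with an estimated correlation). Among stromal cell markers, 0 were higher, 12 lower and 7 not called, or 1 and 14 adjusted over the list alone. Collagens and matrix (median log2 -0.29, adjusted p = 8.31e-10, 0.272 with an estimated correlation) and interferon-stimulated genes (median log2 -0.48, adjusted p = 4.28e-05, 0.204 with an estimated correlation) were lower. Among collagens and matrix, 2 were higher, 24 lower and 7 not called, or 3 and 26 adjusted over the list alone. ER stress and ATF4 targets were higher (median log2 0.18, adjusted p = 9.11e-06, 0.204 with an estimated correlation). Among ER stress and ATF4 targets, 8 were higher, 0 lower and 17 not called, or 10 and 0 adjusted over the list alone.

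Between 4 h and 6 h 1506 genes were called, 722 higher and 784 lower at 6 h, and 1365 with the score as a covariate. The contrast left out the vehicle libraries, but they were in the fit and shared its estimate of the spread. The heat shock genes Dnajb1 (-0.76), Hspa1b (-0.66), Hspa1a (-0.65) and Hsph1 (-0.45), the early genes Fosb (-0.70), Egr1 (-0.61), Atf3 (-0.60) and Fos (-0.52) and the NF-kB genes Ptgs2 (-0.54), Nfkb1 (-0.54), Tnfaip3 (-0.52) and Icam1 (-0.48) were lower at 6 h. So were Lif (107 ± 11 against 171 ± 16.4 CPM, log2 -0.67, adjusted p = 1.61e-05) and Cxcl2 (20.3 ± 1.31 against 33.8 ± 5.40 CPM, log2 -0.73). Il1rl1, the receptor for IL-33 (759 ± 21.1 against 322 ± 25.0 CPM, log2 1.24, adjusted p = 1.28e-09), Mmp13 (32.1 ± 14.1 against 9.92 ± 1.05 CPM, log2 1.69), Mmp3 (0.58), the acute-phase gene Saa3 (24.3 ± 4.44 against 8.88 ± 0.322 CPM, log2 1.45) and Tnc (0.87) were higher. Heat shock genes (median log2 -0.34, adjusted p = 1.08e-16, 0.0304 with an estimated correlation) and stromal cell markers (median log2 -0.30, adjusted p = 1.67e-09, 0.0304 with an estimated correlation) were lower as lists, and both calls held. Chemokines and cytokines had a median of 0.04 and a mean of -0.01 and were not called.

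**Figure D2:**
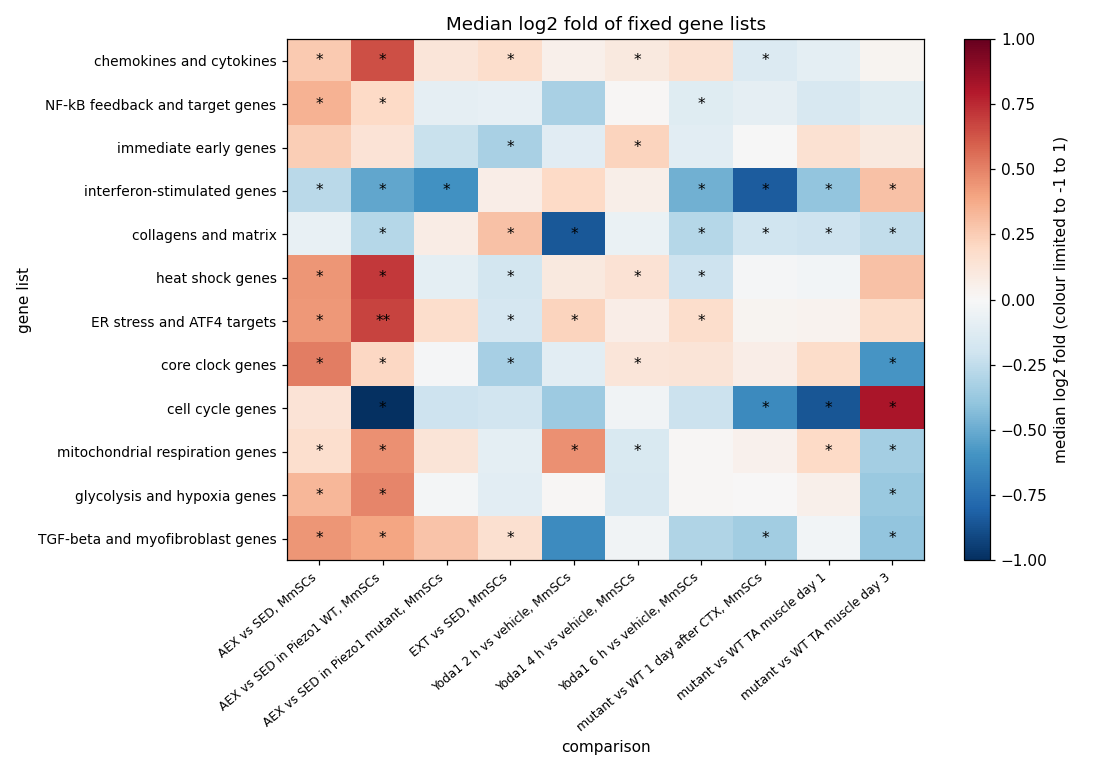
Median log2 fold of 12 fixed gene lists (vertical axis) in 10 comparisons (horizontal axis), with colour limited to log2 -1 to 1, where 1 asterisk stands for a camera adjusted p under 0.05 and a pair also for an estimated correlation. ER stress and ATF4 targets after AEX in WT MmSCs had a median of 0.67.

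Sets taken from 1 cohort were then tested in the others. The genes higher after AEX (33 genes) were higher in the WT cohort's AEX comparison (median log2 0.48, adjusted p = 8.96e-13, 0.0687 with an estimated correlation). They were also higher after EXT (median log2 0.30, adjusted p = 5.34e-10, 0.0433 with an estimated correlation) and in the labelled mutants after AEX (median log2 0.20, adjusted p = 2.88e-05, 0.211 with an estimated correlation). They were lower in labelled mutant than in WT MmSCs after AEX (median log2 -0.25, adjusted p = 5.31e-05, 0.211 with an estimated correlation), and the interaction was negative (median log2 -0.19, adjusted p = 0.00219, 0.266 with an estimated correlation). In Yoda1 they were lower at 2 h (median log2 -0.23, adjusted p = 0.0206, 0.211 with an estimated correlation), not called at 4 h (median log2 -0.04, adjusted p = 0.239), and higher at 6 h (median log2 0.08, adjusted p = 0.0252, 0.0978 with an estimated correlation) and at 6 h against 4 h (median log2 0.15, adjusted p = 4.45e-04, 0.0433 with an estimated correlation). The 200 genes with the strongest rise after 4 h of Yoda1 were lower after AEX (median log2 -0.28, adjusted p = 4.42e-10, 0.188 with an estimated correlation) and after EXT (median log2 -0.11, adjusted p = 0.0153, 0.788 with an estimated correlation), where the median ran from -0.24 to 0.0213 without 1 library and was -0.00469 with up to 500 genes. They were not called at 2 h of Yoda1 in the other cohort (median log2 -0.18, adjusted p = 0.0650), with 6 genes higher and 24 lower. After AEX they were not called in the WT cohort (median log2 0.05, adjusted p = 0.481) and were higher in the labelled mutants (median log2 0.49, adjusted p = 1.88e-28, 0.0234 with an estimated correlation). Their interaction of genotype with AEX was positive (median log2 0.44, adjusted p = 2.79e-15, 0.0759 with an estimated correlation). At rest they were lower in labelled mutants than in WT (median log2 -0.49, adjusted p = 9.34e-29, 0.0234 with an estimated correlation). With the score of the genes that varied together as a covariate, the medians in the labelled mutants after AEX, in the interaction and at rest were 0.0276, -0.0498 and 0.0261 (unadjusted p = 0.937, 0.998 and 0.979). That score was -1.20 to -0.501 in the labelled mutant SED libraries and -0.0678 to 0.674 in those of WT. The covariate therefore also removes part of the difference between genotypes at rest. Of 173 genes that varied together in other cohorts, 112 were among the 493 genes higher at 4 h, the source of the 200. The change of the medians was thus partly built in. Of the 8 comparisons tested with a set taken from 2 h of Yoda1, 5 had the opposite direction.

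One day after CTX, labelled mutant MmSCs were compared with WT MmSCs (n = 3 each). Genes of cell division were lower in the labelled mutants: Plk1, a kinase of mitosis (8.86 ± 0.631 against 37.4 ± 10.9 CPM, log2 -2.08, adjusted p = 2.81e-04), Ube2c (21.5 ± 1.99 against 73.5 ± 24.1 CPM, log2 -1.78), Ccnb2 (-1.77), Ccnb1 (-1.68) and Cenpa (-2.46). Interferon-stimulated genes were lower, among them Ifi44 (-1.91), Oas2 (-1.75), Isg15 (-1.56) and Usp18 (-1.31). Lower too were the interferon-induced chemokine Cxcl9 (3.98 ± 0.379 against 13.3 ± 7.79 CPM, log2 -1.75) and Ccl20 (3.85 ± 1.26 against 13.7 ± 4.52 CPM, log2 -1.84). Il1b (7.42 ± 2.29 against 0.335 ± 0.580 CPM, log2 4.39, adjusted p = 0.0196), and the myeloid gene Lyz2 (6.02 ± 1.10 against 0.671 ± 0.739 CPM, log2 3.13, adjusted p = 0.00618), were higher, both at low counts in sorted stromal cells. The placental growth factor Pgf (42.6 ± 10.5 against 16.9 ± 3.44 CPM, log2 1.34, adjusted p = 0.00345), Klf3, Pygl and the clock gene Hlf were higher (log2 1.15, 0.89 and 1.26). The TGF-beta and matrix genes Acta2 (-1.08), Cilp (-0.70), Ltbp2 (-0.70), Col3a1 (-0.49), Col1a2 (-0.43) and Col5a1 (-0.40) were lower (adjusted p 8.76e-04 to 0.0451). On chromosome 2, Tmem87a (3.42 ± 1.06 against 54.5 ± 15 CPM, log2 -4.00, adjusted p = 5.24e-05), Wt1 (1.32 ± 0.649 against 20.4 ± 10.2 CPM, log2 -3.95) and Duoxa1 (6.89 ± 1.28 against 38.7 ± 12.4 CPM, log2 -2.50, chromosome 2 from 122302191 to 122313730) had the largest falls.

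After CTX 232 of 12957 genes were called in MmSCs, 57 higher and 175 lower. Cell cycle genes were lower (median log2 -0.64, adjusted p = 9.97e-38, 0.128 with an estimated correlation). Among cell cycle genes, 2 were higher, 20 lower and 6 not called, or 5 and 22 adjusted over the list alone. Interferon-stimulated genes were lower (median log2 -0.83, adjusted p = 2.52e-37, 0.174 with an estimated correlation). Among interferon-stimulated genes, 0 were higher, 13 lower and 18 not called, or 0 and 23 adjusted over the list alone. Collagens and matrix (median log2 -0.20, adjusted p = 6.89e-09, 0.579 with an estimated correlation), TGF-beta genes (median log2 -0.35, adjusted p = 3.51e-05, 0.325 with an estimated correlation) and chemokines and cytokines (median log2 -0.14, adjusted p = 0.0128, 0.740 with an estimated correlation) were also lower. Without WT 2 and WT 3 the count was 132 and 387, and without mutant 1, 2 and 3 it was 123, 98 and 127. DESeq2 called 366.

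In WT TA muscle, days 1, 3 and 7 after CTX were compared to describe regeneration (n = 4, 3 and 3). By day 3 the genes that fuse myoblasts had risen, Mymk (294 ± 89.3 against 1.31 ± 0.604 CPM, log2 7.78, adjusted p = 3.16e-14) and Mymx (70.9 ± 19.9 against 0.249 ± 0.180 CPM, log2 8.04). So had embryonic myosin Myh3 (679.8 ± 382 against 3.51 ± 1.03 CPM, log2 7.60, adjusted p = 8.19e-09, chromosome 11 from 67078300 to 67102291), neonatal myosin Myh8 and the fetal acetylcholine receptor subunit Chrng (log2 5.61 and 5.81). The macrophage genes Gpnmb (4.37), Spp1 (2.63) and C1qb (2.07), the matrix genes Postn (3.04), Col5a1 (2.05) and Col3a1 (1.72) and the mitotic genes Ccnb2 (3.29), Cdc20 (2.72) and Bub1b (2.63) also rose. Chemokines of the first day fell, Ccl7 (28.2 ± 13.1 against 413 ± 53.7 CPM, log2 -3.88), Ccl2 (45.7 ± 8.34 against 539 ± 48.7 CPM, log2 -3.56) and Cxcl5 (-2.68). Lower as well were the neutrophil genes Trem1 (-4.12), Cxcr2 (-3.45) and S100a9 (-2.97), the injury marker Nmrk2 (-4.29) and the endothelial genes Flt1 (-2.06), Sox17 (-1.64) and Ptprb (-1.52). Piezo1 fell too (log2 -0.73, adjusted p = 0.00749). In all 4149 genes were called, 2189 higher and 1960 lower. Myogenic regeneration genes were higher (median log2 3.71, adjusted p = 3.20e-50, 5.97e-04 with an estimated correlation) and endothelial markers lower (median log2 -1.17, adjusted p = 8.94e-17, 0.0185 with an estimated correlation), and both calls held.

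From day 3 to day 7 adult fibre genes rose, Myh2 (1694 ± 478 against 108 ± 41.2 CPM, log2 3.97, chromosome 11 from 67171027 to 67197517), Myh1 (21445 ± 3213 against 2701 ± 397 CPM, log2 2.99), Casq1 (2.83) and Mybpc1 (2.75). Higher too were the mitochondrial genes Ppargc1a (1.84), Idh3a (1.86) and Uqcrfs1 (1.88) and the endothelial genes Cdh5 (1.41), Kdr (1.34) and Sox18 (1.60). The macrophage genes Spp1 (-5.15), Arg1 (-6.03), Itgam (-4.13) and Ly6c2 (-3.48), the neutrophil collagenase Mmp8 (-5.78), and the cell cycle genes Rrm2 (-3.25), Plk1 (-3.09) and Ccnb1 (-2.81) fell. The interferon-stimulated Oas3 (-2.77), Oas1a (-2.62) and Mx1 (-2.51), and the fusion and early muscle genes Mymx (-4.03), Chrng (-3.39) and Myog (-2.93) were lower as well. Of 15499 genes 6590 were called, 3112 higher and 3478 lower. Monocyte and macrophage markers were lower (median log2 -2.57, adjusted p = 4.27e-27, 0.0305 with an estimated correlation) and mitochondrial respiration genes higher (median log2 1.63, adjusted p = 1.96e-32, 0.131 with an estimated correlation). Among mitochondrial respiration genes, 30 were higher, 0 lower and 0 not called, or 30 and 0 adjusted over the list alone.

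**Figure D3:**
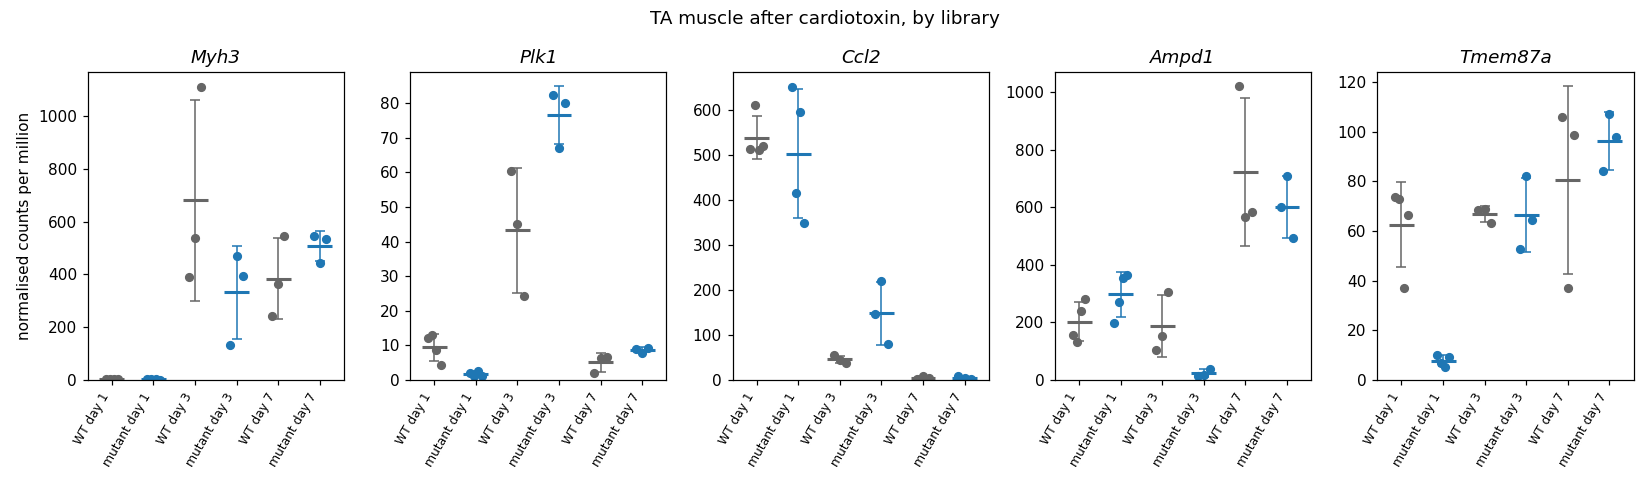
Normalised CPM of Myh3, Plk1, Ccl2, Ampd1 and Tmem87a (vertical axes) in TA muscle libraries (points) at days 1, 3 and 7 after CTX in WT and labelled mutant mice, with means and SD bars. At day 3 the labelled mutants had means of 148 CPM of Ccl2 against 45.7 in WT and of 22.6 CPM of Ampd1 against 187.

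At day 1, labelled mutant and WT TA muscle (n = 4 each) differed in 12 genes, all lower in the labelled mutants. Tmem87a, a Golgi and membrane protein, fell most (7.76 ± 2.29 against 62.5 ± 17.3 CPM, log2 -3.01, adjusted p = 1.15e-05, chromosome 2 from 120355312 to 120404113). Depdc7, Pla2g4e and Gatm on the same chromosome were lower (log2 -1.57, -1.38 and -1.23), as were Psmc3ip (-1.68) and the mitotic genes Plk1 (1.70 ± 0.752 against 9.47 ± 3.90 CPM, log2 -2.47, adjusted p = 0.00944) and Cdc20 (2.66 ± 0.730 against 10.2 ± 4.96 CPM, log2 -1.94). Cell cycle genes were lower as a list (median log2 -0.86, adjusted p = 1.79e-29, 0.218 with an estimated correlation), and so were interferon-stimulated genes (median log2 -0.39, adjusted p = 1.07e-07, 0.588 with an estimated correlation). Among cell cycle genes, 0 were higher, 2 lower and 26 not called, or 0 and 19 adjusted over the list alone. The count was 5 without WT 1 and 6, 7, 6 and 6 without mutant 1, 2, 3 and 4. DESeq2 called 42.

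At day 3 (n = 3 each), adult fibre genes were lower in labelled mutant TA muscle: the AMP deaminase Ampd1 (22.6 ± 13.6 against 187 ± 107 CPM, log2 -3.03, adjusted p = 3.82e-04), the calcium pump Atp2a1 (2024 ± 1109 against 11729 ± 5702 CPM, log2 -2.53, adjusted p = 1.60e-04), Pvalb (95.3 ± 52.6 against 682 ± 287 CPM, log2 -2.83, adjusted p = 3.16e-05), Mybpc2 (-2.50), Myh4 (-2.37), Scn4b (-3.12), Myoz3 (-2.73) and Ky (-2.69). The fibre-associated glycolysis genes Aldoa (-1.60), Slc16a3 (-1.72), Gapdh (-1.30) and Hk2 (-0.88), Tpm2 and Tpm1 (log2 -1.86 and -1.82), Des (-1.59), and Ppargc1a (-1.41) were lower as well. So were the clock repressor Nr1d1 (26.2 ± 8.64 against 60.4 ± 8.68 CPM, log2 -1.18, adjusted p = 8.28e-04), Amotl1 (64.9 ± 21.8 against 173 ± 17.0 CPM, log2 -1.41, adjusted p = 4.83e-05), Actc1 (-1.67) and the macrophage arginase Arg1 (5.65 ± 0.902 against 22.0 ± 20.9 CPM, log2 -1.97). The monocyte chemokines Ccl7 (108 ± 76.1 against 28.2 ± 13.1 CPM, log2 1.95, adjusted p = 0.00863), Ccl2 (148 ± 69.9 against 45.7 ± 8.34 CPM, log2 1.70, adjusted p = 0.0125) and Ccl12 (16.1 ± 8.22 against 5.26 ± 0.623 CPM, log2 1.63, adjusted p = 0.0146, chromosome 11 from 82101845 to 82103400) were higher. The stress cytokine Gdf15 (2.21), Fosl1 (1.36), Myc (0.76) and the cell cycle genes Nusap1 (1.22), Birc5 (1.18), Bub1 (1.08) and Rrm2 (1.08) were higher too (adjusted p 0.0129 to 0.0324).

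Of 15499 genes 1392 were called at day 3, 405 higher and 987 lower. Muscle fibre genes were lower (median log2 -1.78, adjusted p = 9.81e-37, 0.116 with an estimated correlation). Among muscle fibre genes, 0 were higher, 21 lower and 3 not called, or 0 and 23 adjusted over the list alone. Cell cycle genes were higher (median log2 0.81, adjusted p = 2.15e-16, 0.229 with an estimated correlation). Among cell cycle genes, 14 were higher, 0 lower and 14 not called, or 26 and 0 adjusted over the list alone. TGF-beta genes (median log2 -0.39, adjusted p = 0.0239, 0.203 with an estimated correlation), myogenic regeneration genes (median log2 -0.40, adjusted p = 0.0141, 0.671 with an estimated correlation) and mural cell markers (median log2 -0.35, adjusted p = 0.0121, 0.490 with an estimated correlation) were lower, and monocyte and macrophage markers were not called (median log2 0.18, adjusted p = 0.113). Neutrophil markers were not called, with a negative median (-0.39) and a test in the positive direction. Without WT 3 the count was 431 (23 higher and 408 lower) and without mutant 2 it was 698 (79 and 619). A fit with only the day 3 libraries called 257, 18 higher and 239 lower.

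At day 7 edgeR called 0 genes between labelled mutant and WT TA muscle (n = 3 each), 737 had unadjusted p under 0.05, and DESeq2 called 0. Simulated changes of log2 1 and 2 were recovered in 52.2% and 82.5% of cases among 14813 genes. Adipocyte genes (median log2 0.46, adjusted p = 0.0196, 0.747 with an estimated correlation) and monocyte and macrophage markers (median log2 0.22, adjusted p = 0.0196, 0.747 with an estimated correlation) were higher as lists. Without 1 library the mean log2 of the adipocyte list ran from 0.0200 to 0.96, and the direction of its test turned in the course. The interaction of genotype with day, which tests whether the difference between genotypes changed over days 1, 3 and 7, was called for 603 genes. Between days 1 and 3 the difference rose for Plk1 (3.29), Tmem87a (3.01), Nusap1 (2.80), Cdc20 (2.66), Ccnb1 (2.57) and Birc5 (2.46) and fell for Kcnc1 (-3.87), Scn4b (-3.77), Ampd1 (-3.59), Aqp4 (-3.49), Pvalb (-3.07) and Myh4 (-2.70), with adjusted p 2.70e-04 to 0.00946. Without WT day 3 replicate 3, WT day 1 replicate 2 or mutant day 1 replicate 4 the interaction called 243, 390 and 393 genes. Without mutant day 3 replicate 3 it called 837, and DESeq2 called 1053. Lists were tested here on the change between days 1 and 3 alone, and not jointly. Cell cycle genes (median log2 1.68, adjusted p = 7.31e-32, 0.0721 with an estimated correlation) and muscle fibre genes (median log2 -2.02, adjusted p = 2.21e-31, 0.0721 with an estimated correlation) moved in opposite directions.

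Uninjured tissue was compared to ask what the floxed allele does without injury. In quadriceps (n = 3 each) edgeR called 0 of 11856 genes, 771 had unadjusted p under 0.05, and DESeq2 called 0. The count was 1 without mutant 1. Simulated changes of log2 1 and 2 were recovered in 78.1% and 99.0% of cases among 11668 genes. Immediate early genes were higher (median log2 0.25, adjusted p = 6.63e-06, 0.149 with an estimated correlation). Among immediate early genes, 0 were higher, 0 lower and 16 not called, or 4 and 0 adjusted over the list alone. Endothelial markers were higher (median log2 0.18, adjusted p = 0.00283, 0.580 with an estimated correlation) and monocyte and macrophage markers lower (median log2 -0.22, adjusted p = 0.0147, 0.580 with an estimated correlation). In uninjured heart edgeR called 0 genes, 985 had unadjusted p under 0.05 and DESeq2 called 19. The count was 5 without WT 3 and 4 without mutant 2, and 67.0% and 81.1% of simulated changes were recovered among 16480 genes. Collagens and matrix (median log2 0.18, adjusted p = 4.73e-08, 0.309 with an estimated correlation) and interferon-stimulated genes (median log2 0.44, adjusted p = 6.86e-12, 0.340 with an estimated correlation) were higher as lists in the labelled mutant hearts. Among collagens and matrix, 0 were higher, 0 lower and 33 not called, or 6 and 0 adjusted over the list alone. Cell cycle genes (median log2 0.64, adjusted p = 2.45e-11, 0.309 with an estimated correlation) and cardiac stress genes (median log2 0.35, adjusted p = 0.00638, 0.309 with an estimated correlation) were higher too.

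In hearts taken 3 days after CTX in skeletal muscle (n = 3 each), 10 of 16735 genes were called, 1 higher and 9 lower in the labelled mutants. The giant sarcomere gene Ttn, Syne1, which anchors nuclei (46.1 ± 7.96 against 107 ± 11.3 CPM, log2 -1.22, adjusted p = 0.0381, chromosome 10 from 5020917 to 5551482), and the endothelial phosphatase Ptprb (156 ± 6.81 against 256 ± 7.85 CPM, log2 -0.72, adjusted p = 0.0381) were lower. The noncoding RNA Kcnq1ot1 (31.9 ± 7.57 against 78.5 ± 2.06 CPM, log2 -1.30), Megf9 (-1.58), Dlc1 (-1.15), Samd4 (-1.11) and Leng8 (-1.0) were also lower, and the kinase Mapkapk2 was higher (136 ± 2.73 against 83.9 ± 2.57 CPM, log2 0.70, adjusted p = 0.0381). Kcnq1ot1 lies antisense to Kcnq1, and whether the counts were stranded is not given in the sources used here. Mitochondrial respiration genes (median log2 0.26, adjusted p = 1.90e-08, 0.774 with an estimated correlation) and glucocorticoid-induced genes (median log2 0.40, adjusted p = 1.20e-04, 0.774 with an estimated correlation) were higher. Among mitochondrial respiration genes, 0 were higher, 0 lower and 30 not called, or 20 and 1 adjusted over the list alone. Mitochondrial transcripts took 13.6% of counts in the labelled mutants and 12.1% in WT. Genes detected numbered 21567, 22077 and 21942 in mutant 1, 2 and 3 and 23931 to 24246 in WT. Library quality was therefore not separated from genotype here. The set of genes that varied together between single libraries had a median log2 of -0.43, and its score was 0.212, -0.460 and -0.830 in mutant 1, 2 and 3 and 0.306 to 0.423 in WT. No gene was called without WT 2, WT 3, WT 4 or mutant 3, 2 without mutant 2 and 1236 without mutant 1. The unadjusted p was under 0.05 for 3091 genes, and DESeq2 called 880.

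In uninjured liver (n = 4 each) edgeR called 0 of 14534 genes, 525 had unadjusted p under 0.05, and DESeq2 called 23. The count was 1 without mutant 1 and 3 without mutant 4. Simulated changes of log2 1 and 2 were recovered in 49.5% and 83.2% of cases among 14095 genes. Red blood cell genes were higher in the labelled mutants (median log2 1.75, adjusted p = 3.48e-18, 0.0792 with an estimated correlation). Among red blood cell genes, 0 were higher, 0 lower and 7 not called, or 5 and 0 adjusted over the list alone. Interferon-stimulated genes were higher (median log2 0.39, adjusted p = 3.13e-07, 0.628 with an estimated correlation) and mitochondrial respiration genes lower (median log2 -0.16, adjusted p = 5.75e-07, 0.931 with an estimated correlation). Hepatocyte genes were not called (median log2 0.02, adjusted p = 0.891).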

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

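The tests in this part were chosen after results were seen, except for the test of G and C content and the regrouping of samples. The main comparisons and the fits without 1 library were also set before, but the use of those fits on a pattern was chosen after. Of 36 sets of replicate values searched for a library apart from its group, about 1 in 20 would stand out by chance. In WT TA muscle at day 1, Mymk, which fuses myoblasts, was at 0.410 CPM in 1 library and at 1.54 to 1.70 CPM in the others. The interaction of genotype with day in TA muscle, a difference between groups, was called for 603 genes. Between days 1 and 3 the difference between the labelled mutants and WT rose by log2 3.29 in Plk1, 3.01 in Tmem87a, 2.80 in Nusap1, 2.66 in Cdc20, 2.57 in Ccnb1, 2.55 in Knl1, 2.54 in Kif2c and 2.46 in Birc5. It was negative in Cited4 (-4.88), Kcnc1 (-3.87), Scn4b (-3.77), Ampd1 (-3.59), Aqp4 (-3.49), Car8 (-3.44), Asb15 (-3.43) and Kcng4 (-3.37).

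A set of genes rose together after 4 h and 6 h of Yoda1 and in the labelled mutants after AEX. Variation between single libraries that does not come from the treatment may account for a part of it. Of the genes higher at 4 h, 21.4% (103 of 482) varied with the set in the other cohorts, against 1.23% of all genes (Fisher's exact test, p = 5.00e-109). Genes that defined the set or were measured in under 20 other libraries were left out. The shares were 12.7% at 6 h and 68.8% (11 of 16) in the labelled mutants. The genes that defined the set were chosen after values were seen, and some had risen in these comparisons. Genes that vary with them were therefore likely to be among the higher genes. Fisher's test also treats genes as independent, so its p cannot tell variation between libraries from a shared response. G and C content at the start of transcripts was excluded as the whole cause, since genes outside the set as rich in G and C had a median log2 of 0.0894 (quartiles -0.10 and 0.28, 2224 genes) against 0.70 in the set. A response to Yoda1 stays open: the set had a median log2 of -0.18 at 2 h in the other cohort, but 2 h may be too early, and the 4 h and 6 h libraries share 1 set of vehicle libraries.

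Genes on chromosome 2 were lower in the labelled mutants 1 day after CTX, in TA muscle and in MmSCs. A stretch of the chromosome that differs between the mice used at day 1 may account for it. Of lower genes with a coordinate, 5 of 11 in TA muscle lay in 1 window of 30 Mb (95000001 to 125000000, 155 genes tested). In MmSCs 18 of 174 lay in 1 such window (105000001 to 135000000, 200 tested). Without the cell cycle list it was 5 of 9 and 15 of 154. Each had a permutation p of 0.0001, the smallest that 10000 permutations allow. The cell division genes Knl1, Ckap2l, Knstrn and Cdc25b, not on that list, stayed among the 15, and Knl1 among the 5. Crowding free of all cell division genes was therefore not tested. A fall of Tmem87a in every labelled mutant was excluded, as it was called lower in 0 of the 8 other comparisons of genotypes (lowest log2 -0.35). The other genes of the window were not checked this way. In TA muscle at day 3, Pla2g4e had a lower mean in the labelled mutants (9.47 ± 2.63 against 28.4 ± 8.88 CPM). Knl1, Gatm and Depdc7 had higher means there. Tmem87a was at 5.73 to 12.3 CPM in every library of the Yoda1 4 h and 6 h cohort, whose labels give no genotype. It was at 9.08 and 12.8 CPM in 1 AEX and 1 EXT library named WT (27.6 to 34.7 CPM in the others of those groups). An effect of Piezo1 limited to day 1 stays open, and Piezo1 itself was not called lower (log2 -0.28 in MmSCs, adjusted p = 0.190).

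Muscle fibre genes were lower and cell cycle genes higher in labelled mutant TA muscle at day 3. Whether a smaller share of muscle fibres was the only change could not be decided. Mural cell markers were also lower (median log2 -0.35, interval -0.65 to -0.17). That interval came from resampling the marker genes and not the libraries. The call of the mural list did not hold with an estimated correlation. A single library was excluded for the 2 lists, as in 6 of 6 fits without 1 of them the fibre list stayed lower and the cell cycle list higher (mean log2 0.60 to 1.07), although the number of higher genes ran from 23 to 542. An earlier stage of regeneration could not be told apart, since no day between 1 and 3 was measured. Genes lower at day 7 than at day 1 in WT had a median log2 of 0.19 (quartiles -0.0787 and 0.42, 3536 genes), and genes higher at day 7 one of -0.29 (quartiles -0.77 and 0.00144, 3360 genes).

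Regrouping the samples within a comparison asked how often as many genes are called. In TA muscle 1 of 35 regroupings at day 1 (highest other 4), 1 of 35 for day 3 against day 1 in WT (highest other 1467) and 2 of 100 for genotype by day (highest other 770) did so. Each share was under 0.05, but the shares were not adjusted over the comparisons regrouped, so chance is not excluded. For genotype by day, 1 regrouping called more genes than the real groups. For liver 35 of 35 (highest other 24) and for genotype by AEX 100 of 100 (highest other 49) did so, with 0 genes called in the real groups, and the 24 and 49 point to a structure of the samples whose cause was not tested.

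With 3 libraries against 3 the 10 regroupings are too few for a share under 0.05. As many genes were called in 1 of 10, the real groups, for AEX (highest other 0), EXT (1), Yoda1 at 4 h (1), at 6 h (0) and at 6 h against 4 h (1), AEX in WT (2) and in the labelled mutants (1), and genotype after CTX in MmSCs (1). The same held for genotype at day 3 in TA muscle (5), day 7 against day 3 in WT (13) and heart at day 3 (0). For genotype at SED in MmSCs 3 of 10 did so, and the highest other, 18, is several times the real count of 1, which points to a structure of the samples whose cause was not tested. For genotype after AEX (0), in TA muscle at day 7 (1), in quadriceps (4) and in uninjured heart (3), 10 of 10 did so, with 0 genes called in the real groups.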

How the results depend on the processing

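The settings with genes that varied together, Y-linked expression, thinned counts and only the libraries compared were chosen after results were seen, and the other tests were set before. A count is said to have moved where it changed by more than a factor of 1.5. Named genes and lists are counted per comparison, so the same gene can enter under several comparisons. RLE scaling moved 0 of 22 counts of called genes. It left 861 named genes and 203 lists the same and made 7 and 3 weaker. In all, the number of calls of named genes, counted per comparison, was 848, 841 with RLE scaling and 809 with no filter. With DESeq2 and without the genes that varied together it was 817 each, where 8 lost the call, and the other 23 had no adjusted p in DESeq2 or were among the genes left out. The 206 list calls became 203, 200 and 203 with RLE scaling, with no filter and without those genes.

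DESeq2 moved 13 counts and left 9 the same. It called 432 genes for AEX, 218 for EXT, 443 for AEX in WT, 75 for AEX in the labelled mutants, 53 for genotype at SED, 2 for genotype after AEX and 1 for genotype by AEX. It called 366 for genotype after CTX in MmSCs, 42 in TA muscle at day 1, 1053 for genotype by day, 19 in uninjured heart, 880 in heart at day 3 and 23 in liver. It left 837 named genes the same and made 8 weaker. The cause was not tested.

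No filter on low counts moved 15 counts and left 7 the same. They became 650 for AEX, 344 for EXT, 398 for AEX in WT, 119 for AEX in the labelled mutants, 111 for genotype at SED, 20 for genotype after AEX, 15 for genotype by AEX and 586 for genotype after CTX in MmSCs. In tissue they became 92 and 10 in TA muscle at days 1 and 7, 1208 for genotype by day, 20 in quadriceps, 64 in uninjured heart, 695 in heart at day 3 and 1 in liver. Of named genes 829 stayed the same and 39 were weaker, and of lists 200 and 6. The cause was not tested.

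With the estimated correlation between genes, 7 of 206 list calls remained, as did 7 of the 15 transferred sets with an unadjusted p under 0.05. By adjusted p, 4 of 13 sets remained. Only the setting of the correlation differed, so the calls that were lost depend on the preset of 0.01.

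Leaving out 1 library moved 62 counts and left 94 the same. The lowest and highest counts were 1 and 975 for AEX, 12 and 117 for EXT, 272 and 3047 for Yoda1 at 2 h, 456 and 656 at 4 h, 15 and 230 for AEX in WT, 1 and 34 for AEX in the labelled mutants, 0 and 91 for genotype at SED, 0 and 4 for genotype by AEX and 98 and 387 for genotype after CTX in MmSCs. In TA muscle they were 5 and 18 at day 1, 431 and 1721 at day 3 and 243 and 837 for genotype by day. They were 0 and 1 in quadriceps, 0 and 5 in uninjured heart, 0 and 1236 in heart at day 3 and 0 and 3 in liver. Of the values of named genes 4563 stayed the same, 1365 were weaker, 1 was stronger and 11, all of Piezo1, reversed.

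The log2 of Piezo1 without 1 library ran from -0.29 to 0.0702 for genotype by AEX, -0.12 to 0.28 in TA muscle at day 3, -0.15 to 0.0583 at day 7, -0.0272 to 0.58 in quadriceps, -0.26 to 0.0482 in uninjured heart and -0.63 to 0.25 in liver. Of lists 1309 stayed the same, 212 were weaker and 2 reversed by the direction of the test. These were collagens and matrix in TA muscle at day 3 (mean log2 -0.37 to -0.0539) and adipocyte genes at day 7 (0.0200 to 0.96). The median of the Yoda1-up set ran from -0.24 to 0.0213 in EXT, -0.0692 to 0.14 in AEX in WT, -0.0642 to 0.0668 in genotype after AEX and -0.0362 to 0.15 in genotype after CTX. That of the AEX-up set ran from -0.18 to 0.14 in genotype at SED. Each of these fits had 1 sample fewer, and no other cause was tested.

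With the replicate number as a block, 14 counts stayed the same and 3 moved, to 19 for EXT, 460 for Yoda1 at 2 h and 137 in heart at day 3. The red blood cell list reversed in heart at day 3 (mean log2 -0.93). Of named genes 724 stayed the same and 88 were not called. At 2 h of Yoda1 and in heart at day 3 the groups share only 2 replicate numbers, and the cause was not tested. Pairing by number was not borne out, as correlations of libraries with the same number ran from -0.161 to 0.204 and no pair of groups had all of them over 0.1. No block was fitted in the cohort with both genotypes and AEX, where each number in a column name is that of 1 sample by library name and of another by title.

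Without the genes that varied together between libraries, 20 counts stayed the same and 2 moved, to 2 for AEX in the labelled mutants, where 17 of 22 higher genes had been among those left out, and to 0 for genotype at SED, where the 1 called gene had been. In AEX in WT the median of the Yoda1-up set kept its sign (0.0477, then 0.0261) while the direction of its test turned, and the cause was not tested.

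With the score of the genes that varied together as a covariate, 4 counts stayed the same and 4 moved, to 3 at 4 h of Yoda1, 28 at 6 h, 0 for AEX in the labelled mutants and 0 for genotype at SED. At 4 h the log2 reversed in Fam174a (-0.45), Plbd2 (-0.23), Rps2 (-0.23), Mtg2 (0.30), Il11 (-0.0703), Tnip1 (0.0312), Csrnp1 (-0.20), Igfbp3 (-0.16), Ltbp2 (0.33), Cx3cr1 (2.23) and the clock list (-0.0723). At 6 h it reversed in Mmp10 (-1.07), Nop9 (-0.13), Fam174a (-0.43), Il11 (-0.17), Tnip1 (0.0630), Ier2 (-0.93), Gbp7 (0.51) and Ajuba (-0.63). Nfil3 (-0.19), Pcna (-0.53), Igfbp3 (-0.56), Bambi (-1.53), Cd55 (0.0780), Itga7 (0.0745), and the interferon (0.11) and heat shock lists (0.0694) reversed too. The score separates Yoda1 from vehicle libraries, so the covariate takes away part of the treatment by construction.

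The same score as a covariate reversed, for genotype at SED, the lists of NF-kB (-0.0153), immediate early (-0.14), heat shock (-0.10), glucocorticoid (-0.0901), clock (-0.0961) and glycolysis genes (-0.26). The Yoda1-up (0.0261) and AEX-up sets (-0.19) reversed there as well. For genotype by AEX it reversed the immediate early list (0.0951) and the Yoda1-up set (-0.0498), and the cell cycle list turned by the direction of its test alone (mean log2 0.15). The Yoda1-up set also reversed in AEX in WT (-0.0101) and in genotype after AEX (0.00643). In AEX in the labelled mutants its median fell from 0.49 to 0.0276, near 0. The score rests on genes that include Rnf187, among the largest rises at 4 h of Yoda1, so the changes of this set may be partly built in. The cause was not tested.

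Other sizes and sources of the Yoda1-up set turned the direction of its test. With up to 50 genes its median was -0.0128 in genotype after AEX (-0.0335 with up to 200), and with up to 500 genes it changed sign there (0.0145). In EXT it was -0.00469 with up to 500 genes and -0.11 with up to 200. The set from 2 h of Yoda1 was at -0.0719 in AEX in the labelled mutants, 0.14 in genotype at SED, 0.0140 in genotype after AEX, -0.12 in genotype by AEX and -0.0538 in genotype after CTX. The cause was not tested.

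In a fit of only the libraries of the 2 groups compared, 257 genes were called in TA muscle at day 3, with fewer samples in the fit, and the other 4 counts stayed the same. With Y-linked expression as a covariate and with thinned counts the count of the comparison stayed the same. Thinned to the shallowest library, 2 h of Yoda1 gave 1482 called genes against 1437, which tests unequal depth alone, and how far low depth limits the calls was not tested. Of simulated changes of log2 1, 31.2% were recovered at 2 h of Yoda1, 36.4% for genotype after AEX, 49.5% in liver and 78.1% in quadriceps.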

Other observations

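The tests in this part were those of the comparisons, and no tests were added for it. In WT TA muscle from day 1 to day 3, troponins of developing muscle rose, Tnnt2 (from 4.56 ± 0.514 to 206 ± 67.4 CPM), Tnni1 (from 6.13 ± 3.77 to 236 ± 121 CPM) and Tnnc1 (from 5.16 ± 1.47 to 88.4 ± 42.2 CPM). The fibroblast genes Lrrc15 (log2 4.77) and Cthrc1 (log2 3.34) rose with them. Thbd, an anticoagulant receptor of endothelium, went from 507 ± 63.5 to 37.5 ± 0.321 CPM, and Apln, a peptide of sprouting vessels, from 103 ± 21.5 to 6.47 ± 1.52 CPM.

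In labelled mutant TA muscle at day 3, the stretch effector Tead1 (log2 -0.79, adjusted p = 5.34e-04) and the muscle mitochondrial regulator Perm1 (log2 -2.55, adjusted p = 0.00539) were lower than in WT, as was Abcc9, a potassium channel subunit (log2 -1.45, adjusted p = 2.40e-04). The fatty acid carrier Cd36 was higher (log2 0.63, adjusted p = 0.00454).

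Mitochondrial transcripts took 2.08% of counts on average in labelled mutant TA muscle at day 3 and 3.07% in WT, and 6.26% and 5.43% at day 1. In heart at day 3 they took 13.6% in the labelled mutants and 12.1% in WT.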
